A study of Mus musculus with 6 samples.

How the data were processed

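The series held 6 whole-lung samples from mice, each hybridized to 1 Affymetrix array of 45037 probe sets and each a pool of 3 animals, 18 mice in all. The deposited values were signal intensities on a linear scale, with a lowest value of 10 and a highest of 11513.01, per the file headers and the values themselves. How the authors summarised and scaled the probe signals was not given in the sources used here. RNA was labelled with biotin as antisense RNA after cDNA synthesis, per the labels' protocols, and freezing and column extraction were described for the 4 transgenic samples only. No value was missing, no column was left without a sample, and no Affymetrix control probe set was in the table.

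From the deposited intensity values, the 6 arrays were quantile normalized, values below the 20th percentile of all values (15.46, log2 3.95) were raised to it, and log2 was taken. A value at this floor is an upper limit, so a change measured against it is a lower bound in size. Probe sets whose mean lay above the 40th percentile were kept, 27022 of 45037. A gene symbol came from the platform annotation: 34945 probe sets carried 1 symbol, 932 several and 9160 none. Of those with 1 symbol, 34741 matched a gene name in the GRCm38.p6 reference table and 0 needed an updated name. The kept probe sets stood for 13215 genes, and 3973 kept probe sets had no symbol or several.

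Each probe set was fitted with limma (version 3.58.1, R 4.3.3) in a linear model with group and sex as terms over all 6 arrays, which left 2 residual degrees of freedom and a prior of 2.77. A second model with transgene (both durations together), sex and their interaction gave the interaction (prior 2.48). P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a probe set passed at an adjusted p below 0.05. A gene was called changed only where it passed. Animals were pooled, and no group had replicate pools of the same sex. In the model with group and sex, the residual spread was therefore how far the female and male changes between groups differed. It mixed the spread between pools with any difference in response between the sexes, and these cannot be separated. With 2 pools a group, the number of arrays limited the precision of every comparison.

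Gene groups were tested with camera at its preset correlation between genes of 0.01, with the brightest 1-symbol probe set for each gene, on 40 lists, of which 39 had at least 5 measured genes. The same lists were tested with a correlation estimated from the residuals, and with fry. Camera asks whether a list moved relative to all other genes. The estimated correlation rested on 2 residual degrees of freedom, and its adjusted p is given beside the preset one. List members were also adjusted over their list alone. The alternatives were the values as deposited, arrays centred on their medians, a floor at the 40th percentile, log2(value + 16) with no floor, no filter on dim probe sets and a filter at the 60th percentile. Probe sets with an _x_at, _s_at or _a_at suffix were also left out, 1 value per gene (the mean of its probe sets) was used, and lists were tested on the mean of a gene's kept probe sets. In the test, the sex term, the arrays of other groups, or each array in turn were left out, and the variances were moderated with trend and robust settings or not at all. For changes shared by both sexes, 1.5-fold was tried in place of 2-fold.

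Genes named for a comparison were the 10 highest and 10 lowest that passed and changed in the same direction in female and male pools, each at its smallest-p probe set with 1 symbol, with predicted and clone-named genes skipped. For female against male, the direction had to hold in all 3 groups, and for the interaction 5 genes were named each way. Where too few passed, the places went to the genes with the largest value of the smaller of the 2 sexes' changes. Up to 4 members of each list that passed were named by absolute change, and Bmpr2, Tagln, Id1, Id3, Smad6 and the sex-linked markers were always given. These rules, the lists, the comparisons and all alternatives except the one on probe sets with exactly 1 gene symbol were fixed before the data were examined.

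The model was tried on simulated arrays with the spread of these data. With 200 probe sets changed at 8 weeks, it called 1.49% of 2-fold, 64.2% of 4-fold and 92.4% of 8-fold changes, with 7 unchanged probe sets called. With 2000 changed, it called 59.7%, 93.7% and 97.9%, with 81 unchanged called. A shift of 1 on the log2 scale put into the cell cycle list gave adjusted p = 4.5e-42 with the preset correlation, 0.16 with the estimated one and 0.0134 with fry, and 0 unchanged lists passed. The simulated probe sets varied independently of each other. The trial therefore could not show how often lists whose genes vary together pass falsely with the preset correlation. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.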

Results

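Gene expression was measured in whole lung from mice with inducible, smooth muscle-targeted expression of a dominant-negative BMP type 2 receptor (BMPR2), the receptor mutated in familial pulmonary arterial hypertension, and from controls. The 6 arrays formed 3 groups of 1 female and 1 male pool: control, transgene activated for 1 week and transgene activated for 8 weeks. The labels gave no activation time for the controls, and the same pair served both durations. Any difference between groups in age, inducer exposure or tissue handling cannot be told apart from the transgene. This holds for every change against control and for 8 weeks against 1 week. Right ventricular pressure was raised in the transgenic mice, per the series description. The series description gave the controls as carrying the transactivator alone. The label of the male control said so, while that of the female control gave only its sex and the FVB/N strain. If its genotype was another, that difference entered every change measured against it, in females and in the transgenic against control comparison. Median deposited intensity was 63.41 and 61.43 in the female and male control pools, 60.22 and 57.1 at 1 week, and 50.49 and 52.92 at 8 weeks, and between 11.1% and 12.5% of probe sets on each array lay at the lowest value of 10. Pools of 1 sex correlated with each other at 0.9336 to 0.9797, and the female and male pools of a group at 0.9391 to 0.9501. Quantile normalization gave probe sets of the same rank the same value on every array, and this tied the strongest signals. Changes in Scgb1a1 (13.36 on all 6 arrays) and Sftpc (13.26 on 5) therefore could not be measured in the chosen processing. The highest deposited values differed between arrays, from 9821.83 to 11513.01.

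The first question was what had changed in the lung after 1 week of transgene activation. Platelet and proliferation genes were higher by camera with the preset correlation. With fry, 0 of 39 lists passed at 1 week (smallest adjusted p 0.476). Platelet and megakaryocyte genes had a median log2 change of 0.81 (10 of 11 genes higher in both sexes, adjusted p = 6.4e-09 and 0.566 with an estimated correlation). The largest values were those of the platelet receptor Clec1b (1.11), the platelet glycoprotein Gp9 (1.09), neurogranin (Nrgn 0.96) and the platelet tubulin Tubb1 (0.95). Cell cycle genes rose by a median of 0.56 (19 of 26, adjusted p = 8.3e-11 and 0.566 with an estimated correlation). The largest were those of Ube2c (1.31), which marks mitotic proteins for degradation, the mitotic kinase Cdk1 (1.29), the DNA topoisomerase Top2a (1.18) and the proliferation marker Mki67 (0.96). The members of these lists that rose numbered 8 and 8 when adjusted over the list alone and 0 and 0 over all genes tested. Both lists passed without any 1 array, with the platelet median at 0.45 without the male 1 week pool and the cell cycle median at 0.35 without the male control.

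Structural and airway genes moved at the same time. Extracellular matrix genes rose by a median of 0.31 (21 of 27 higher in both sexes, adjusted p = 1.74e-06 and 0.566 with an estimated correlation). The 3 that rose over the list alone were elastin, the elastic fibre protein of vessel walls (Eln 1.33), Col15a1 (1.08) and the collagen-binding proteoglycan lumican (Lum 0.87), against 0 over all genes. Tenascin C (Tnc 0.84) came next without passing, at 0.09 in females and 1.59 in males. Ciliated cell markers rose by 0.37 (14 of 16, adjusted p = 1.74e-06 and 0.566), with Tekt4 at 0.66 and the cilia-forming transcription factor Foxj1 at 0.57. Erythroid genes rose by 0.49 (6 of 8, adjusted p = 0.000453 and 0.566), with the heme synthesis enzyme Alas2 at 1.05, Hbb-b2 at 1.02 and Slc4a1 at 0.91. Complement and acute phase genes rose by 0.24 (adjusted p = 0.000147 and 0.566) and adipose genes by 0.44 (0.00116 and 0.566). Mesothelial markers (0.34, 0.62 in females and 0.10 in males, adjusted p = 0.0147 and 0.628) and club and other secretory airway markers (0.25, 0.0198 and 0.654) also rose. So did skeletal muscle genes (0.29, 0.0159 and 0.566, with the myosin light chain Myl1, at the floor on 1 array, at 1.66) and NK cell markers (0.21, 0.02 and 0.566, with the granzyme Gzma at 0.69).

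Leaving out 1 array ended the call for most of these lists. Extracellular matrix and erythroid genes passed without any 1 array, with the erythroid median at 0.30 without the female control. Without the female control, complement (0.10, adjusted p = 0.217), adipose (0.36, 0.13), mesothelial (0.04, 0.74) and NK cell genes (0.19, 0.371) did not pass, and the ciliated and club medians were 0.60 and 0.43. Without the male control, ciliated (0.15, 0.0733), club (0.0056, 0.733) and skeletal muscle genes (0.35, 0.237) did not, and complement, mesothelial and NK cell genes stood at 0.48, 0.73 and 0.49. Without the female 1 week pool, adipose (−0.02, 0.727), mesothelial (0.28, 0.0782) and NK cell genes (0.18, 0.272) did not, and skeletal muscle genes stood at 0.55. Without the male 1 week pool, club (0.18, 0.0865) and skeletal muscle genes (0.11, 0.413) did not, and NK cell genes stood at 0.42. Processing moved some as well. Without suffixed probe sets (_x_at, _s_at and _a_at), erythroid genes stood at 0.07 (adjusted p = 0.714), NK cell markers did not pass (0.102) and club markers stood at 0.44. The erythroid median was 0.21 with 1 value per gene, and with the mean of a gene's kept probe sets it was 0.24 and the extracellular matrix median 0.20. With no filter on dim probe sets, adipose (0.33, 0.125), mesothelial (0.34, 0.0526) and NK cell genes (0.19, 0.0969) did not pass, nor did the last 2 without the sex term (0.0638 and 0.0562). Mesothelial markers stood at 0.56 with the filter at the 60th percentile and NK cell markers at 0.14 as deposited.

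Fewer groups fell at 1 week. Immediate-early genes, which respond within minutes to growth factors and stress, fell by a median of 0.21 on the log2 scale (17 of 28 lower in both sexes, adjusted p = 5.37e-06 and 0.566 with an estimated correlation), with Atf3 at −1.17 and Egr1 at −0.82. Circadian clock genes had a median of −0.36 (13 of 18, adjusted p = 3.84e-05 and 0.566), with the activator Arntl at 0.97 against the repressors Ciart (−0.89) and Cry1 (−0.66) and the output factor Dbp (−0.81). T cell markers had a median of −0.25 (adjusted p = 0.00493 and 0.595), with the surface receptors Cd6 (−0.76) and Cd5 (−0.66) lowest. The medians for angiogenesis (−0.07, adjusted p = 0.0285), alveolar type 1 (−0.08, 0.0475) and endothelial genes (−0.05, 0.0159) were small, each 0.566 with an estimated correlation, and the endothelial median was 0.03 with arrays centred on their medians. Clock genes passed without any 1 array, with a median of −0.20 without the male control. Without the female control, immediate-early genes (−0.07, adjusted p = 0.654), T cell markers (−0.09, 0.221) and angiogenesis genes (0.0054, 0.371) did not pass, and the endothelial median was −0.16. Without the female 1 week pool, T cell (−0.04, 0.578), angiogenesis (−0.0085, 0.39) and endothelial genes (−0.08, 0.0782) did not. Endothelial genes did not pass without the male control (adjusted p = 0.211) or the male 1 week pool (0.0507) either, angiogenesis genes without either 8 week pool (0.0551), and alveolar type 1 genes without any 1 array (0.0696 to 0.246). Medians grew to −0.41 (immediate-early) and −0.13 (angiogenesis) without the male control, and to −0.45 (T cell) without the male 1 week pool. As deposited, alveolar type 1 (adjusted p = 0.114), angiogenesis (0.0849) and endothelial genes (0.0727) did not pass, nor with arrays centred (0.22, 0.136 and 0.111), where alveolar type 1 stood at −0.02 and angiogenesis at −0.0010. The first 2 did not pass without suffixed probe sets (0.0605 and 0.0586), nor T cell markers with the filter at the 60th percentile (0.0697). Angiogenesis stood at −0.11 with 1 value per gene and −0.12 with the mean of a gene's kept probe sets.

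No single probe set passed at 1 week in limma: 0 of 27022 had an adjusted p below 0.05. The smallest was 0.57, and 1486 had an unadjusted p below 0.05 where 1351 would by chance. Chosen by the smaller of the female and male changes, the genes named, none of which passed, were on the high side the interferon-inducible genes Ifi209 (2.98, adjusted p = 0.766, other probe set −0.15) and Mndal (2.30, 0.57, other probe set at least 4.27, both controls at the floor) and the serine synthesis enzyme Phgdh (2.59, 0.766, other probe sets −0.02 to 0.16). Also named were Fmo5 (2.40, 1 control at the floor), the monocyte chemokine receptor Ccr2 (1.96), Arsk (1.66) and the lubricin gene Prg4 (1.58). The others were the acute phase protein Saa3 (1.46, 0.851), the ubiquitin-conjugating enzyme Ube2c (1.31) and a second elastin probe set (Eln 1.28). On the low side stood Irgc1 (−1.91), Ranbp2 (−1.78), Cntn1 (−1.62), Negr1 (−1.55), Dcaf12 (−1.34), H3f3b (−1.28), Kazn (−1.24), Slc15a2 (−1.13), Yes1 (−1.12) and Zfp458 (−1.09). The first elastin probe set stood at 1.33, and other probe sets of these genes moved less: 0.08 to 0.26 for Fmo5, 0.13 to 0.23 for Ccr2, 0.69 for Arsk, −0.41 to −0.05 for Ranbp2, −0.94 for Cntn1, 0.09 to 0.31 for Dcaf12, 0.03 to 0.12 for Kazn, 0.21 to 0.32 for Slc15a2 and −0.12 to 0.04 for Yes1. The receptor itself and its pathway showed no passing change. Bmpr2 stood at −0.44 (adjusted p = 0.919), −0.08 (the brightest) and −0.22 (the dimmest) on its 3 probe sets. The smooth muscle gene Tagln stood at 0.20, and the BMP-responsive genes Id1, Id3 and Smad6 at −0.20, −0.08 and −0.33. Least squares with no moderation of the variance also called 0. The trend and robust fit called 3 (Mndal on 2 probe sets and 1 probe set with no symbol) and the fit on 1 value per gene called 1 (Mndal, 3.28, adjusted p = 0.0113). These were named after their values were seen.

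After 8 weeks of activation, single genes passed in both directions. Saa3, an acute phase protein made by activated macrophages and epithelium, rose from a log2 intensity of 6.30 ± 0.21 (mean ± SD of 2 pools) to 10.39 ± 0.05, a change of 4.09 ± 0.16 (± standard error; 4.27 in females and 3.91 in males, adjusted p = 0.047). Also rising were the anion exchanger pendrin (Slc26a4 3.59 ± 0.28), the interferon-inducible genes Ifi209 (3.52 ± 0.30) and Mndal (2.61 ± 0.14), and Phgdh (2.95 ± 0.25). The same held for the formin Diaph3 (2.78), the niacin receptor Hcar2 (2.64), the interleukin 1 receptor antagonist Il1rn (2.51), the complement C5a receptor C5ar1 (2.49) and the macrophage gene Ms4a7 (2.40, adjusted p = 0.048). Other probe sets of these genes moved by less for Ifi209 (0.61), Phgdh (0.14 to 1.18) and C5ar1 (0.73), and by more for Mndal (at least 4.74, both controls at the floor). A control pool at the floor also made the changes of Slc26a4 and Diaph3 lower bounds. In total, 161 of 27022 probe sets passed in limma, 56 higher and 105 lower, and with 1 symbol these stood for 46 genes higher and 48 lower. With no filter on dim probe sets, without the sex term, with only the arrays compared, or with least squares, 0 passed. Leaving out 1 array left 1 pool in its group and fewer residual degrees of freedom. The counts of those fits therefore cannot show how far a single array carried the result. Tested on probe sets with exactly 1 symbol alone, a choice made after the data were seen, only Saa3 passed (adjusted p = 0.0388).

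**Figure D1:**
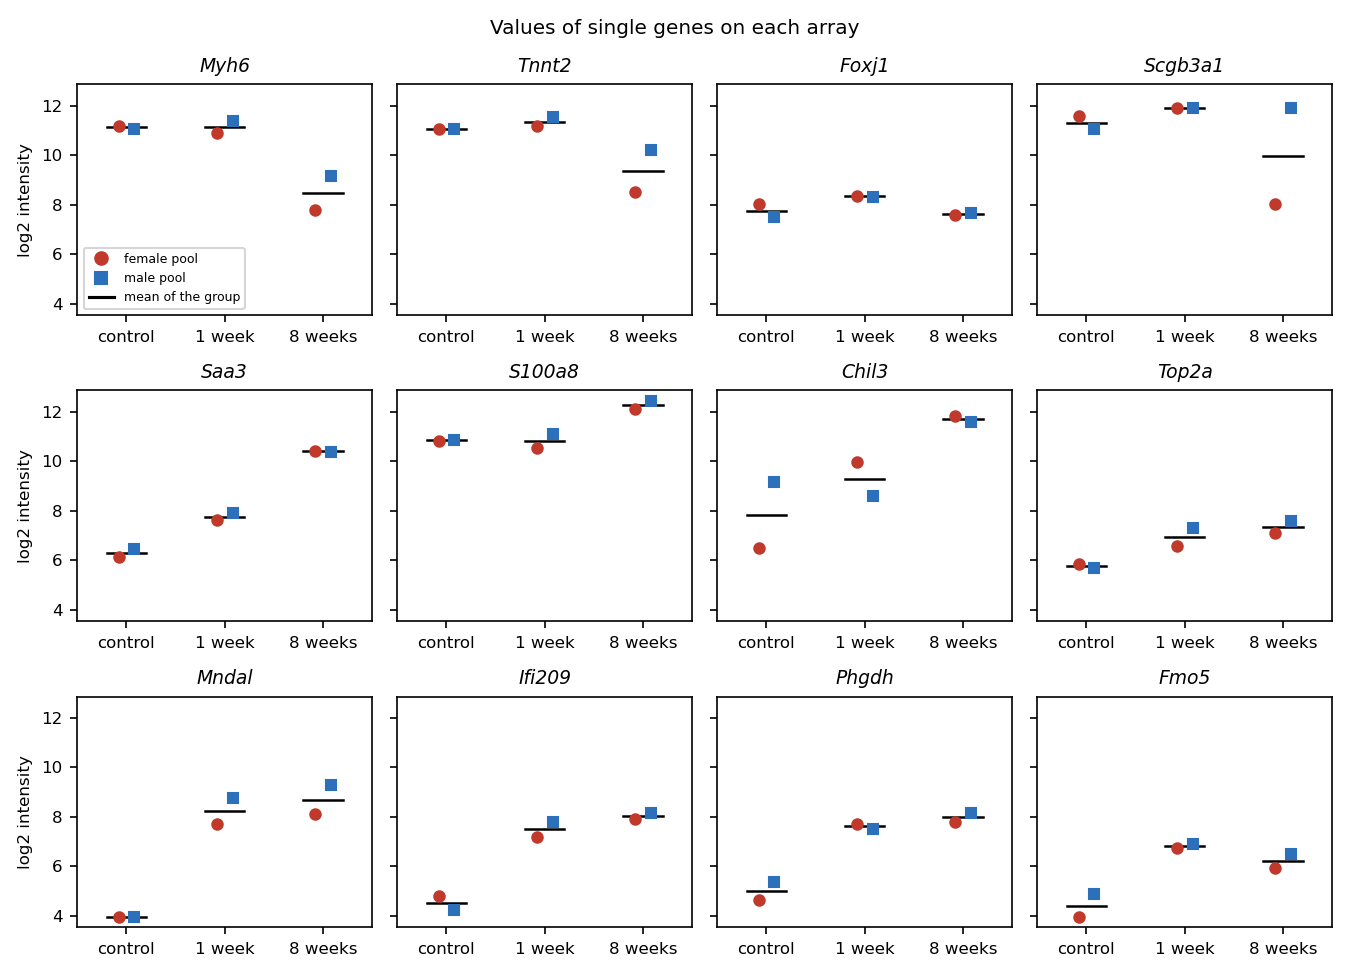
Log2 intensity (vertical axis) of 12 genes in the control, 1 week and 8 week pools, with each point 1 pool and the line the group mean. Saa3 rose at 8 weeks by 4.27 in the female and 3.91 in the male pool, while Myh6 was lower by a larger amount in the female pool (7.80 against 11.18 in its control) than in the male pool (9.17 against 11.06).

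Neutrophil, macrophage, cell cycle, complement and alveolar type 2 lists rose at 8 weeks, while T cell, NK cell, B cell, mast cell and cytokine lists did not pass. These calls are those of camera with the preset correlation, and with fry only neutrophil markers passed, 1 of 39 lists. Neutrophil markers rose by a median of 1.16 (13 of 14 higher in both sexes, adjusted p = 8.31e-08, 0.56 with an estimated correlation and 0.00107 with fry). The largest values were those of the neutrophil collagenase Mmp8 (1.96), the calprotectin subunit S100a9 (1.76, adjusted p = 0.0589), the lectin receptor Clec4d (1.60) and the siderophore-binding protein Lcn2 (1.54). In this list 11 members rose over the list alone and 4 over all genes. These 4 were Mmp8, Clec4d and, named after their values were seen, the gelatinase Mmp9 (1.52) and the receptor Trem1 (1.5). Macrophage and monocyte markers rose by 1.10 (20 of 24, adjusted p = 8.53e-08 and 0.56 with an estimated correlation). The largest values were those of the chitinase-like protein Chil3 (3.89), the alveolar macrophage lectin Siglecf (2.67), the proton pump subunit Atp6v0d2 (2.41) and the fatty acid-binding protein Fabp1 (2.24), and the list held 19 rising and 1 falling over the list alone and 1 rising over all genes. Cell cycle genes rose by 0.76 (24 of 26, adjusted p = 4.47e-08 and 0.56), with the largest values for Cdk1 at 1.86, Top2a at 1.60, the checkpoint kinase Bub1 at 1.54 and Ccna2 at 1.46. Of these genes 15 passed over the list alone against 1 over all genes. Complement and acute phase genes rose by 0.40 (adjusted p = 0.0134 and 0.654; 5 over the list alone and 2 over all genes), with Lcn2 at 1.54 and the glycoprotein Lrg1 at 1.45 after Saa3 and Il1rn. That list did not pass without the female control (0.24, adjusted p = 0.0645) or the female 8 week pool (0.29, 0.0509), and stood at 0.60 without the male control. Alveolar type 2 markers rose by 0.31 (13 of 14, adjusted p = 0.00288 and 0.718; 4 over the list alone and 0 over all genes), with the calcium-binding protein S100g at 1.52, the alarmin Il33 at 1.30, the fatty acid-binding protein Fabp5 at 0.83 and the surfactant protease Napsa at 0.83. The other 4 lists passed without any 1 array. Complement genes stood at 0.12 as deposited, 0.25 with no filter and 0.17 with the filter at the 60th percentile. Neutrophil markers stood at 0.76 with no filter or without suffixed probe sets, and alveolar type 2 markers at 0.55 with arrays centred and 0.50 without suffixed probe sets.

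Cardiac and smooth muscle genes fell at 8 weeks. Cardiac muscle genes, which in lung samples come from the sleeves of the pulmonary veins or attached heart tissue, had a median of −1.46 (18 of 22 lower in both sexes, adjusted p = 6.3e-09 and 0.56 with an estimated correlation). The fall was larger in females (−2.54) than in males (−0.55). Titin, the giant spring protein of the sarcomere (Ttn −3.83 ± 0.32, female 8 week pool at the floor, other probe sets −3.06 to −1.31), and the calcium pump regulator phospholamban (Pln −2.35, others −2.59 to −1.61) passed. The cardiac myosin Myh6 (−2.63), the calcium release channel Ryr2 (−2.53) and the sarcomere protein Tcap (−2.03) were next in the list after Ttn and did not pass over all genes. Over the list alone, 8 cardiac genes fell. Smooth muscle contractile genes, the compartment in which the transgene was expressed, fell by a median of 0.30 on the log2 scale (21 of 23, adjusted p = 1.29e-08 and 0.56). The intermediate filament protein synemin (Synm −1.15) was the 1 gene that fell over the list alone, and 0 did over all genes. The smooth muscle myosin Myh11 stood at −1.51, the potassium channel subunit Kcnmb1 at −0.88 and the co-activator myocardin (Myocd) at −0.79. Both lists passed without any 1 array. The cardiac median was −0.81 without the female control, −0.60 without the female 8 week pool and −2.45 without the male one, and the smooth muscle median −0.45 without the male control and −0.13 with arrays centred.

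Airway and vascular lists had negative medians as well. Ciliated cell markers fell by 0.54 on the log2 scale (15 of 16 lower in both sexes, adjusted p = 1.29e-08 and 0.56 with an estimated correlation; 9 over the list alone and 0 over all genes). The cilia genes Rsph1, Cfap126 and Enkur stood at −1.06, −0.90 and −0.79, and Cdhr3 at −0.71. Endothelial markers had a median of −0.17 (adjusted p = 6.92e-04 and 0.56; 0.01 with arrays centred on their medians), with the arterial transcription factor Sox17 at −0.62, Vwf at −0.59 and Sox18 at −0.45. Angiogenesis genes stood at −0.16 (adjusted p = 0.00365 and 0.56; −0.00032 with arrays centred), with Vegfc at −0.71, Notch3 at −0.59 and Vegfa at −0.55 against Pgf at 0.86. Club and other secretory airway markers stood at −0.22 (adjusted p = 0.0119 and 0.718), and at 0.03 with arrays centred. The median was −0.47 in females and 0 in males, with the tied member Scgb1a1 counted as 0. The largest member, the airway defence protein Bpifa1, was −5.39 or lower in females, where the 8 week pool lay at the floor, and 0.90 in males. The club list did not pass without the female control (−0.09, adjusted p = 0.462) or the female 8 week pool (−0.03, 0.839), and stood at −0.49 without the male control and −0.45 without the male 8 week pool. Circadian clock genes had a median of −0.44 (adjusted p = 8.89e-04 and 0.605), with the output factor Hlf at −1.76 and Usp2 at −1.09 against the repressor Nfil3 at 1.78 and Arntl at 1.04. Immediate-early genes had a median of −0.41 (adjusted p = 0.00128 and 0.718), −0.60 in females and 0.04 in males. Atf3 stood at −0.91, Egr1 at −0.87 and Jun, the 1 that fell over the list alone, at −0.85, against Egr2 at 0.88. This list did not pass without the female control (0.0036, adjusted p = 0.335) or the female 8 week pool (−0.11, 0.172), and stood at −0.65 without the male 8 week pool. The other lists of this paragraph passed without any 1 array. The ciliated median was −0.85 without the male control, and the clock median −0.26 without the male control, −0.70 without the female 8 week pool and −0.17 without the male one. As deposited, club markers did not pass (−0.24, adjusted p = 0.115), and the endothelial and angiogenesis medians were −0.27 and −0.27. With arrays centred, clock and immediate-early genes stood at −0.25 and −0.25, and with 1 value per gene clock genes stood at −0.69.

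**Figure D2:**
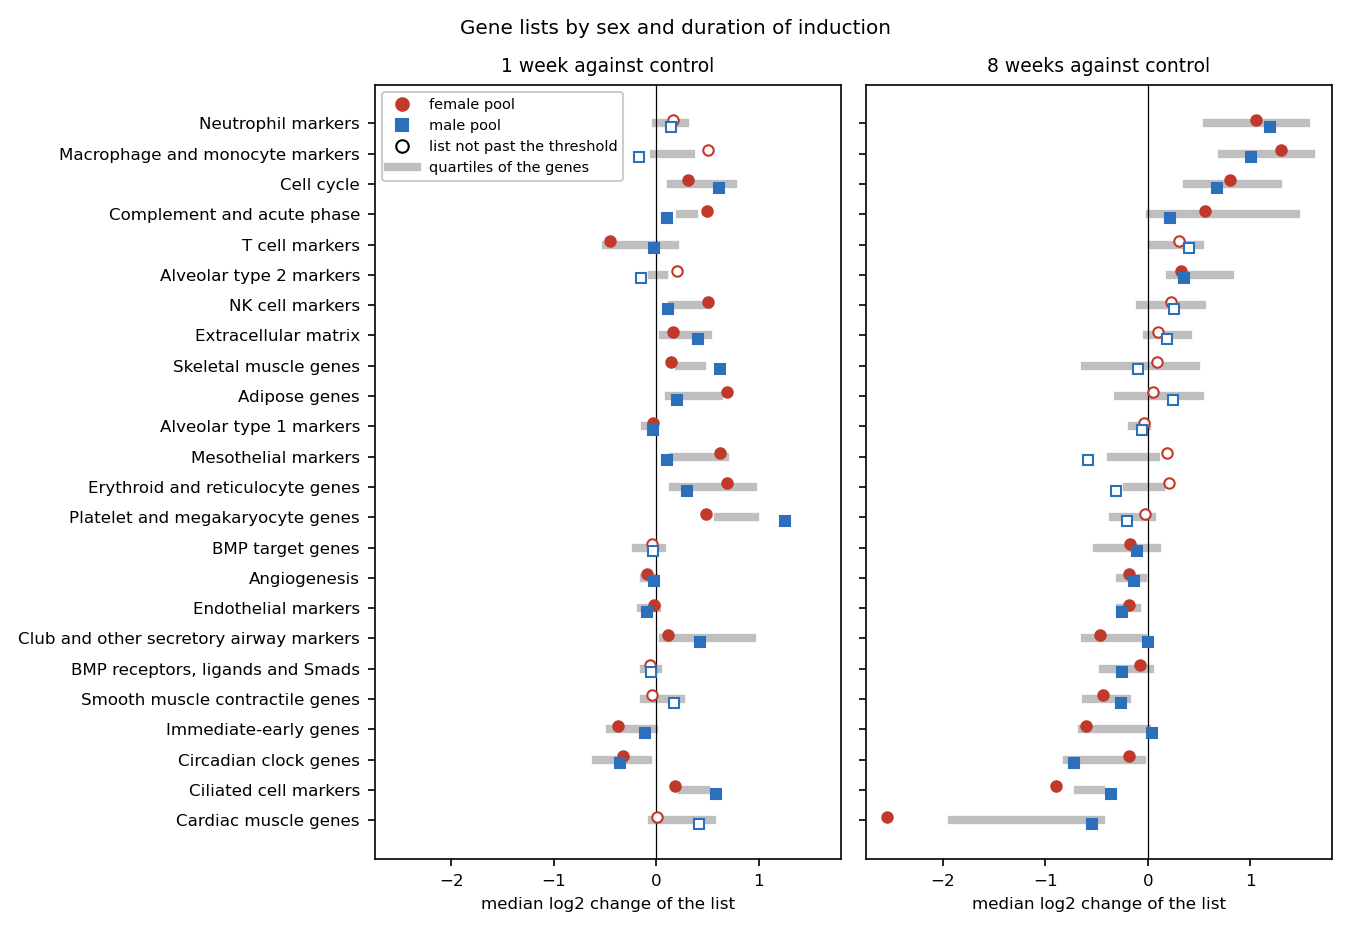
Median log2 change against control (horizontal axis) of 24 gene lists at 1 week (left) and 8 weeks (right), for the female pool (red circles) and the male pool (blue squares), with open symbols for lists that did not pass and grey bars for the quartiles of the list's genes. At 8 weeks neutrophil (1.16) and macrophage (1.10) lists lay to the right in both sexes, and the cardiac list lay at −2.54 in females and −0.55 in males.

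BMP signalling lists had small, negative medians. BMP receptors, ligands and Smads had a median of −0.24 at 8 weeks (9 of 20 lower in both sexes, adjusted p = 0.00709 and 0.56 with an estimated correlation). Bmp6 stood at −0.71, Bmpr1b at −0.67, Bmp4 at −0.58 and Bmp7 at −0.58 (−1.53 in females and 0.37 in males). BMP target genes had a median of −0.12 (8 of 14, adjusted p = 0.0284 and 0.56; 6.484e-04 with arrays centred on their medians). The inhibitor of differentiation Id4 at −1.03 and the inhibitory Smad6 at −0.82 (adjusted p = 0.102) were the 2 that fell over the list alone, and 0 did over all genes. Sost, at the floor on 2 arrays, stood at −0.81 and Atoh8 at 0.72. The receptor list did not pass without the male control (−0.09, adjusted p = 0.0512) or the male 8 week pool (−0.13, 0.0568). The target list did not pass without the female 8 week pool (−0.09, 0.104), and stood at −0.05 without the male control and −0.29 without the male 8 week pool. Nor did it pass as deposited (−0.27, 0.0922), and it stood at −0.07 with no filter, −0.04 with the filter at the 60th percentile and −0.05 with 1 value per gene. The receptor list stood at −0.05 with arrays centred. Id1 stood at −0.50 (adjusted p = 0.155) and Id3 at −0.02 (0.949). Bmpr2 stood at −0.93 ± 0.21 (adjusted p = 0.108), −0.26 (0.327, the brightest) and 0.01 (0.981, the dimmest) on its 3 probe sets, in the order given for 1 week. The last stood at −0.26 in the values as deposited. Tagln, whose promoter drove the transactivator, stood at −0.15 (adjusted p = 0.54), and at 0.03 with arrays centred. Whether any Bmpr2 probe set read the transgene was not given in the sources used here.

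The remaining named decreases at 8 weeks were Zc3h4 (−3.27), the endocytic scaffold Itsn2 (−2.43), Dock9 (−2.30), the kinase Smg1 (−2.30), the noradrenaline transporter Slc6a2 (−2.29), Zfp458 (−2.25), the tetraspanin Tspan18 (−2.25) and the phospholipase Plcb4 (−2.25), all with an adjusted p of 0.047 to 0.048 (male 8 week pool at the floor for Tspan18). Other probe sets of these genes moved far less: −0.05 for Zc3h4, −1.05 to 0.01 for Itsn2, −0.63 to −0.26 for Dock9, −0.20 to 0.27 for Smg1, −0.25 to 0.58 for Slc6a2, −0.67 to 1.02 for Tspan18 and −0.64 for Plcb4. Probe sets with no symbol made up 53 of the 105 lower calls and 2 of the 56 higher ones, and their median change was −0.18 against 0.05 for probe sets with 1 symbol. The smallest adjusted p was 0.047, shared by many probe sets, and 1363 probe sets lay below 0.10. The count was 461 (76 higher, 385 lower) in the values as deposited and 705 (318 and 387) with arrays centred on their medians.

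Female and male pools were then compared for the size of their separate responses over 13215 genes. At 8 weeks 159 genes were at least 2-fold higher and 30 at least 2-fold lower in both sexes, against 8 that went opposite ways (r = 0.50). At 1 week 12 were higher and 3 lower in both, against 8 opposite (r = 0.123). For 8 weeks against 1 week 134 were higher and 107 lower in both, against 4 opposite (r = 0.598).

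**Figure D3:**
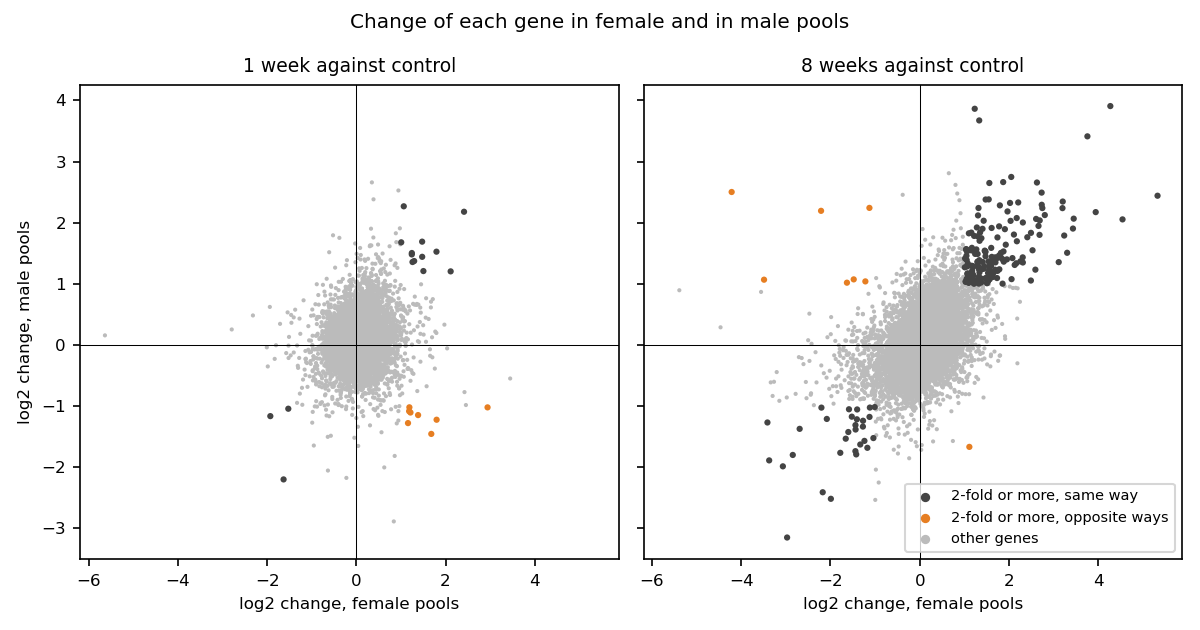
Log2 change against control in the male pool (vertical axis) and the female pool (horizontal axis) at 1 week and 8 weeks, with each point a gene, black for at least 2-fold the same way in both, orange for opposite ways and grey for the rest. At 8 weeks 159 genes were higher and 30 lower in both sexes, and at 1 week 12 and 3.

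The comparison of 8 weeks with 1 week asked what separated long from short activation. Only neutrophil markers, 1 of 39 lists, passed with fry. Ciliated cell markers were lower at 8 weeks in all 16 genes in both sexes (median −0.95, adjusted p = 2.13e-13 and 0.562 with an estimated correlation). All 16 fell over the list alone, and 0 did over all genes. Cardiac muscle genes were lower by 1.90 on the log2 scale (19 of 22, adjusted p = 1.32e-10 and 0.562; 17 over the list alone). Smooth muscle contractile genes had a median of −0.42 (19 of 23, adjusted p = 9.57e-09 and 0.562; 6 over the list alone), with Myh11 at −1.77, the actin Actg2 at −1.35 and calponin (Cnn1) at −1.04. Neutrophil markers were higher by 1.21 (11 of 14, adjusted p = 1.77e-06, 0.562 with an estimated correlation and 0.00256 with fry; 10 over the list alone). Macrophage and monocyte markers were higher by 0.95 (21 of 24, adjusted p = 4.42e-08 and 0.562; 14 over the list alone). Cytokines and chemokines were higher by 0.46 (16 of 23, adjusted p = 0.0201 and 0.562; 4 over the list alone), with the inflammatory cytokines Il6 at 2.99 and Il18 at 1.58 and the chemokines Cxcl10 at 1.95 and Cxcl2 at 1.88 (Il6 and Cxcl2 at the floor on 1 array each). T cell markers were higher by 0.45 (13 of 16, adjusted p = 0.00236 and 0.635; 4 over the list alone), with Cd6 at 1.37 and Cd5 at 1.09. Platelet genes, higher at 1 week, were lower by 1.07 on the log2 scale at 8 weeks than at 1 week (10 of 11, adjusted p = 6.28e-07 and 0.562; 7 over the list alone). Club cell genes had a median of −0.51 (13 of 15, adjusted p = 2.43e-05 and 0.562; 1 over the list alone). T cell markers did not pass without the female 1 week pool (0.29, adjusted p = 0.0521), and the other lists of this paragraph passed without any 1 array. Without the female 8 week pool the cardiac median was −1.13 and the club median −0.24. Without the male 8 week pool, cytokines stood at 0.16, platelet genes at −0.58 and club genes at −0.77, and without the male 1 week pool platelet genes stood at −0.65. Cytokines did not pass with the filter at the 60th percentile (0.10, adjusted p = 0.577) and stood at 0.23 as deposited, and club genes stood at −0.88 without suffixed probe sets.

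Single genes did not pass between 8 weeks and 1 week: 0 of 27022 in limma, with a smallest adjusted p of 0.101 and 5000 unadjusted p below 0.05. The count was 0 with least squares, 752 with the trend and robust fit and 180 with 1 value per gene. Chosen by the smaller of the female and male changes, the genes named on the high side were the fungal-recognition lectin Clec4n (3.40, adjusted p = 0.106), Hcar2 (3.13, 0.101), Il6 (2.99), Fabp1 (2.86), Diaph3 (2.83), Spata5l1 (2.75), Slc26a4 (2.69), Saa3 (2.63), Siglecf (2.62) and Ms4a6d (2.47). On the low side they were the airway defence protein Bpifb1 (−3.75, adjusted p = 0.209), Ttn (−3.56), Zc3h4 (−2.60), Myh6 (−2.35), Ryr2 (−2.34), Pln (−2.29), Epb41l2 (−2.28), the sarcomere protein Tcap (−2.19), the phosphate transporter Slc20a1 (−1.98) and Limch1 (−1.96). Pools at the floor made the changes of Hcar2, Clec4n, Il6, Spata5l1, Ttn, Myh6 and Limch1 lower bounds in size. Other probe sets stood at 2.54 (Clec4n), 2.67 (Fabp1), 1.84 (Ms4a6d), −2.83 to −0.57 (Ttn), 0.04 (Zc3h4), −2.65 (Myh6), −2.70 to −1.55 (Pln), −0.96 to 0.0033 (Epb41l2), −2.57 (Bpifb1), −0.01 (Slc20a1) and −0.41 to −0.13 (Limch1).

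The 4 transgenic pools together were set against the 2 controls, which averages over both durations. Again 1 of 39 lists, neutrophil markers, passed with fry. A median can pass here although the durations differ: cardiac genes stood at 0.28 and −1.46 at 1 and 8 weeks, ciliated cell markers at 0.37 and −0.54, platelet genes at 0.81 and −0.11, smooth muscle genes at 0.05 and −0.30, and alveolar type 2 markers at −0.04 and 0.31. Cell cycle genes rose by a median of 0.60 (24 of 26 higher in both sexes, adjusted p = 1.11e-10 and 0.56 with an estimated correlation; 14 over the list alone and 0 over all genes). Neutrophil markers rose by 0.72 (13 of 14, adjusted p = 1.72e-07, 0.56 with an estimated correlation and 0.00635 with fry; 8 over the list alone), and macrophage and monocyte markers by 0.69 (18 of 24, adjusted p = 1.16e-06 and 0.583; 14). Complement and acute phase genes rose by 0.32 (adjusted p = 0.000291 and 0.56; 4) and extracellular matrix genes by 0.20 (20 of 27, adjusted p = 0.000807 and 0.56; 5). Alveolar type 2 markers (0.20, adjusted p = 0.0208) and platelet genes (0.31, 0.0333) passed with 0.716 under an estimated correlation. Circadian clock genes fell, with a median of −0.40 (12 of 18 lower in both sexes, adjusted p = 2.29e-05 and 0.56; 1 rose and 2 fell over the list alone). So did immediate-early genes (−0.29, adjusted p = 1.26e-05 and 0.583) and cardiac muscle genes (−0.45, adjusted p = 1.47e-05 and 0.583; −1.11 in females and 0.00 in males). Medians were small for BMP receptors, ligands and Smads (−0.14, adjusted p = 0.00491) and BMP target genes (−0.10, 0.0208), each 0.56 with an estimated correlation, and for ciliated cell markers (−0.10, 0.0155 and 0.716). Centred arrays gave 9.194e-04, 0.01, 0.01 and 0.07 for smooth muscle (−0.12, adjusted p = 0.000143), angiogenesis (−0.11, 0.00248), endothelial (−0.12, 0.000192) and alveolar type 1 genes (−0.06, 0.0249), each 0.56 with an estimated correlation.

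Of these averages, those of cell cycle, neutrophil, macrophage, complement, extracellular matrix, clock and endothelial genes passed without any 1 array. Without the female control, cardiac (0.0014, adjusted p = 0.0821), ciliated (0.07, 0.581), immediate-early (−0.04, 0.405), alveolar type 2 (0.07, 0.48), angiogenesis (−0.06, 0.0895), smooth muscle (−0.08, 0.0553), BMP target (−0.08, 0.0628) and alveolar type 1 genes (−0.07, 0.0606) did not pass. Macrophage markers then stood at 0.41, complement genes at 0.20 and endothelial markers at −0.19. Without the male control, platelet genes (0.11, 0.739), BMP receptors (−0.12, 0.0595) and alveolar type 1 genes (−0.05, 0.139) did not pass. Cardiac genes then stood at −1.11, ciliated at −0.37, complement at 0.52, clock at −0.23, extracellular matrix at 0.13, angiogenesis at −0.19 and BMP target genes at −0.04. Without the female 1 week pool, ciliated (−0.11, 0.0546) and alveolar type 2 genes (0.14, 0.138) did not pass, and platelet genes stood at 0.56. Without the male 1 week pool, platelet (0.08, 0.365) and BMP target genes (−0.05, 0.0653) did not. Without the female 8 week pool, platelet (0.21, 0.19), ciliated (−0.0086, 0.258) and BMP target genes (−0.09, 0.0639) did not, and cardiac and immediate-early genes stood at −0.11 and −0.15. Without the male 8 week pool, alveolar type 1 (−0.03, 0.071) and type 2 genes (0.16, 0.0968) did not, and cardiac, ciliated and platelet genes stood at −0.96, −0.16 and 0.47.

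Processing moved several of these averages. As deposited, alveolar type 1 (−0.11, adjusted p = 0.104) and BMP target genes (−0.19, 0.0745) did not pass, and medians were −0.23 for BMP receptors, −0.17 for angiogenesis, −0.22 for ciliated, 0.19 for complement and 0.15 for platelet genes. With arrays centred, alveolar type 1 (0.3) and platelet genes (0.33, 0.0795) did not pass. Medians were then −0.05 for BMP receptors, −0.0060 for BMP targets, −0.04 for ciliated, −0.16 for immediate-early, 0.36 for alveolar type 2 and 0.325 for extracellular matrix genes. BMP target genes stood at −0.05 with the floor at the 40th percentile, −0.03 with no filter and −0.05 with the filter at the 60th percentile. Platelet genes did not pass with no filter (0.31, adjusted p = 0.115), nor ciliated markers with the filter at the 60th percentile (0.0511), without suffixed probe sets (0.0526) or with 1 value per gene (0.0825). Without suffixed probe sets, alveolar type 1 genes did not pass either (0.132) and BMP receptors stood at −0.09. Alveolar type 1 genes stood at −0.13 with 1 value per gene or the mean of a gene's kept probe sets, and with the latter alveolar type 2 genes did not pass (0.052).

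For single genes in this comparison, 0 of 27022 probe sets passed in limma (smallest adjusted p 0.12, 3794 with an unadjusted p below 0.05). The count was 0 with least squares, 96 with the trend and robust fit and 4 with 1 value per gene (Mndal, Saa3, Ifi209 and Ube2c, named after their values were seen). Chosen by the smaller of the female and male changes, the genes named on the high side were Ifi209 (3.25), Saa3 (2.77, adjusted p = 0.12), Phgdh (2.77), Mndal (2.46, 0.12), Slc26a4 (2.24), Fmo5 (2.09), Arsk (1.71), Ccr2 (1.69), the mitotic checkpoint kinase Bub1b (1.59) and the metalloproteinase inhibitor Timp1 (1.51). On the low side they were Ttn (−2.05), Zc3h4 (−1.97), Ranbp2 (−1.96), Zfp458 (−1.67), Dock9 (−1.55), the nuclear RNA Malat1 (−1.52), the RNA-binding protein Ybx1 (−1.50), Tspan18 (−1.49), Plcb4 (−1.47) and the splicing factor Srrm2 (−1.40). Pools at the floor made those of Slc26a4, Fmo5, Bub1b, Ttn, Ybx1 and Tspan18 lower bounds in size. Other probe sets stood at 0.23 (Ifi209), 0.15 to 0.59 (Phgdh), 4.50 or more (Mndal), 0.04 to 0.17 (Fmo5), 0.82 (Arsk), 0.18 to 0.55 (Ccr2), 0.29 (Bub1b), −1.65 to −1.02 (Ttn), −0.07 (Zc3h4), −0.61 to −0.08 (Ranbp2), −0.35 to −0.26 (Dock9), −0.90 to −0.52 (Malat1), −0.24 (Ybx1), −0.37 to 0.91 (Tspan18), −0.42 (Plcb4) and −0.58 to −0.05 (Srrm2).

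Female and male lungs differed first in the sex-linked markers that were always given. Xist, the RNA that silences 1 X chromosome in females, was higher in females by 5.08 ± 0.16 (adjusted p = 0.00506, other probe sets 3.89 and 6.38). The Y-linked genes were lower. Eif2s3y was lower by 5.58 on the log2 scale (adjusted p = 0.00223), Kdm5d by 3.49 (0.00455), and Uty by 3.90 (0.00684) and 2.94 (0.0117) on 2 of its probe sets, while the third stood at 0.25 (0.672). The passing Y-linked probe sets lay at the floor in all 3 female pools, so their changes were lower bounds in size. Ddx3y had no probe set with 1 symbol. Of 27022 probe sets 2244 passed, 934 higher and 1310 lower in females.

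Among the other differences, the heart hormone atrial natriuretic peptide was lower in females (Nppa −3.41, adjusted p = 0.0136, at the floor in all 3 female pools), and the liver transcription factor Creb3l3 (3.09), the calcium pump Atp2b3 (2.90) and the crystallin-related Cryl1 (3.01, other probe sets −0.21 to 0.12) were higher. Also higher were Trim62 (4.05, others 0.44 to 3.89), the RNA-binding protein Elavl1 (3.90, others 0.09 to 0.41), F8a (3.69, other 0.12), the apoptosis initiator Casp9 (3.38, others −0.64 to −0.01), the ubiquitin ligase Trip12 (2.98, others −0.24 to 0.14) and the orphan nuclear receptor Nr4a3 (2.88, other −0.36). The other genes lower in females were the UDP-galactose transporter Slc35a2 (−2.78, others −0.25 to 0.52), the G protein subunit Gnai3 (−2.71, other 0.32), the splicing factor Sf3b6 (−2.49, others −0.01 to 0.22), Rabepk (−2.24, others −0.19 to 0.22), Stxbp3 (−2.17, other −0.45) and Smim10l1 (−2.16, others −0.32 to −0.16, adjusted p = 0.0362). Other probe sets of the autosomal genes called moved in the same direction in 54.7% of cases, with a median of 0.04 against 0.91 for the called ones. The share was 82.5% for the genes called at 8 weeks. Their called changes were larger (median 1.89, other probe sets 0.559), so the shares are not like for like. F8a lay at the floor in all 3 male pools, and Elavl1, Casp9, Creb3l3, Trip12, Nr4a3, Slc35a2 and Sf3b6 did on 1 or 2 arrays. With least squares, or with no filter on dim probe sets, 0 passed.

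**Figure D4:**
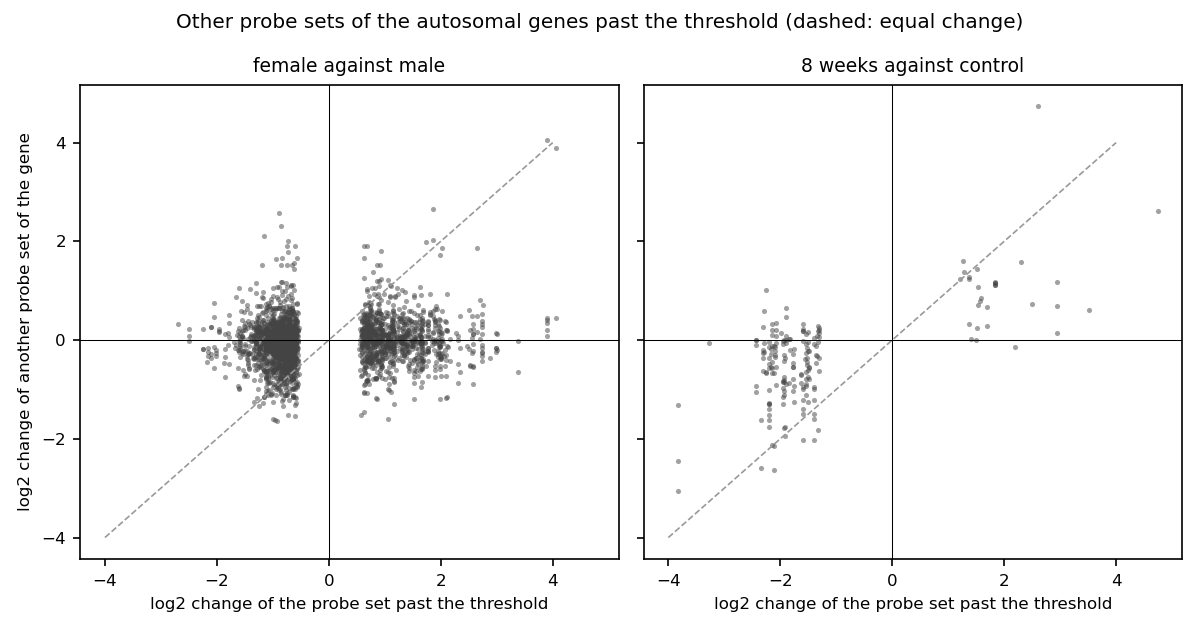
Log2 change of the probe set that passed (horizontal axis) and of another probe set of the same gene (vertical axis), for female against male and for 8 weeks against control, with the dashed line at equal change. Other probe sets moved in the same direction in 54.7% of cases for sex and in 82.5% at 8 weeks, where the called changes were larger (median 1.89 against 0.906).

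The last comparison asked whether the transgene acted differently in the 2 sexes. None of 27022 probe sets passed for the interaction in limma (smallest adjusted p 1). An unadjusted p below 0.05 was found for 636, where 1351 would be expected by chance. The 1 probe set called by least squares was the tied Scgb1a1. The model took both durations together, so differences between 1 and 8 weeks within a sex counted as residual spread. The test therefore cannot show that the sexes responded alike. Of the genes named, the macrophage protein Chil3 changed by 4.39 in females and 0.95 in males (difference 3.44), and the neutrophil chemokine Cxcl2 by −4.93 and 1.33 (−6.26), without passing. Beside them stood the renal transporter Slc22a19 (3.23), the heat shock protein Hspa1a (3.01), the eosinophil ribonuclease Ear3 (2.97) and the zinc transporter Slc39a8 (2.68, other probe set 0.05), and, with the opposite sign, the airway proteins Bpifa1 (−3.49), Reg3g (−3.43) and Bpifb1 (−2.89, other −2.98) and the chemokine Cxcl1 (−3.02, others −5.41 to −4.50). For Cxcl2 and Slc22a19 a control pool lay at the floor, and for Bpifa1 and Reg3g the female 8 week pool.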

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

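The comparisons were fixed beforehand, and the tests of explanations below were chosen after the results had been seen. Between 1 and 8 weeks of activation, 14 gene groups differed by camera with the preset correlation, and none did with an estimated correlation (0 lists, smallest adjusted p 0.562). With fry 1 did, that of neutrophil markers. Each of the 14 is given as the median log2 difference of 8 weeks against 1 week, with the medians against control at 1 and 8 weeks after it.

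Leukocyte and alveolar groups were higher at 8 weeks. Neutrophil markers differed by 1.21 (0.16 and 1.16), macrophage and monocyte markers by 0.953 (0.13 and 1.10), T cell markers by 0.447 (−0.25 and 0.37) and cytokines and chemokines by 0.455 (0.01 and 0.30). Alveolar type 2 markers differed by 0.306 (−0.04 and 0.31) and cell cycle genes by 0.27 (0.56 and 0.76). Blood and lining groups were lower: platelet and megakaryocyte genes by −1.07 (0.81 and −0.11), erythroid and reticulocyte genes by −0.382 (0.49 and −0.10), mesothelial markers by −0.454 (0.34 and −0.08) and endothelial markers by −0.115 (−0.05 and −0.17). Muscle and airway groups were lower as well: cardiac muscle genes by −1.9 (0.28 and −1.46), smooth muscle contractile genes by −0.422 (0.05 and −0.30), ciliated cell markers by −0.952 (0.37 and −0.54) and club and other secretory airway markers by −0.513 (0.25 and −0.22). Cell cycle genes did not pass without the female 1 week pool (0.1023, adjusted p = 0.411) or the female 8 week pool (0.1921, 0.113), and stood at 0.4737 without the male 1 week pool. T cell markers did not without the female 1 week pool (0.2894, 0.0521), mesothelial markers without the male 8 week pool (−0.2045, 0.0666; −0.7658 without the female one), and endothelial markers without any 1 of the 4 transgenic pools (0.0508 to 0.222). Alveolar type 2 markers stood at 0.1605 without the male 1 week pool. Without the male 8 week pool, cytokines stood at 0.156, platelet genes at −0.5764 (−0.6495 without the male 1 week pool) and club markers at −0.7745, and without the female one club markers at −0.2412 and cardiac genes at −1.129. Erythroid genes did not pass with no filter on dim probe sets (−0.3703, adjusted p = 0.0706), without suffixed probe sets (−0.02687, 0.635) or with 1 value per gene (−0.2684, 0.102). Cell cycle and endothelial genes did not pass as deposited (0.1394, 0.0632 and −0.1994, 0.0979) or with arrays centred (0.3214, 0.134 and −0.01742, 0.172), nor endothelial genes without the sex term (0.0544), nor cytokines with the filter at the 60th percentile (0.1007, 0.577; 0.2298 as deposited). Without suffixed probe sets, alveolar type 2 and club markers stood at 0.4966 and −0.877.

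The cardiac and ciliated decreases were weighed further, because both tissues lie near the lung root. Dilution of the lung by incoming leukocytes would lower alveolar markers too, but alveolar type 2 markers had a median of 0.312 and type 1 markers of −0.0511, above the upper quartile of the ciliated markers (−0.459), which spoke against dilution alone. The fixed type 2 list included Sftpc, whose change could not be measured, and Cd74, which was also on the MHC class II list. The type 2 median therefore weighs less than the type 1 median. For less tissue from the lung root in the 8 week pools, the share of cardiac and ciliated genes lower in both sexes (86.8%, 33 of 38) only restated the pattern, and 6 of 15 secretory airway markers, a list not chosen for it, were lower in both. For an effect of the transgene that grows with its duration, the female cardiac median lay at −2 relative to the male one, against a quartile spread of 1.45 within the list. At 1 week no fall was seen, with medians in females and males of 0.00954 and 0.415 (cardiac) and 0.178 and 0.579 (ciliated). These values argue against a fall already under way at 1 week, but not against a transgene effect that began later. Such a later effect and less tissue from the lung root both stayed open and cannot be told apart in these pools. A record of how the lobes were trimmed, or ciliated cell counts in sections, would separate them.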

How the results depend on the processing

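The fit had 2 residual degrees of freedom, and the count of probe sets passing at 8 weeks moved by over 1.5 times with nearly every choice. Of the counts of probe sets or genes, 86 stayed within that range and 48 moved. The 86 include every count of 0 that stayed at 0, where a comparison had called nothing. Of the counts of passing lists, 64 stayed and 8 moved. Of the followed values for single genes, 1780 kept their direction and call, 343 became weaker, 58 stronger and 10 reversed. For lists, 902 kept both, 218 became weaker and 13 reversed. At 8 weeks the neutrophil median ranged from 0.762 to 1.47 and passed in 17 of 18 alternatives, the macrophage median from 0.961 to 1.24 (16 of 18), the cardiac one from −2.45 to −0.601 (16) and the ciliated one from −0.853 to −0.384 (16). All alternatives were planned except the one on probe sets with exactly 1 gene symbol, added after the data were seen. The female and male pools of a group shared a sex term in place of a pairing, and without it 0 probe sets passed at 8 weeks (smallest adjusted p 0.0606). Except where said, the cause of a difference was not tested.

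Scaling moved the counts at 8 weeks (161 in the chosen processing) to 461 in the values as deposited and 705 with each array centred on its median, and shifted the median change of all probe sets from 0.033 to −0.133 and 0.139. As deposited, the Bmpr2 probe set that stood at 0.0096 at 8 weeks was −0.2606. Centred, transgenic against control gave 5 (Mndal on 2 probe sets, Ifi209, Saa3 and 1 without a symbol), and these signs reversed: at 1 week endothelial markers 0.0253; at 8 weeks Tagln 0.03001, Id3 0.1713, BMP target genes 0.0006484, endothelial markers 0.006834 and club markers 0.02815; and for transgenic against control smooth muscle genes 0.0009194, angiogenesis 0.01059, endothelial markers 0.01467 and alveolar type 1 markers 0.07075.

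A floor at the 40th percentile gave 439 at 8 weeks (182 higher, 257 lower). Log2(value + 16) with no floor gave 583 (231 and 352), and 3 for transgenic against control (Saa3, Mndal and 1 without a symbol). With no filter on dim probe sets 0 passed at 8 weeks and 0 for sex, and 25 genes were 2-fold changed the same way in both sexes at 1 week (15 in the chosen processing). A mean above the 60th percentile gave 505 at 8 weeks (223 and 282), 62 for 8 weeks against 1 week and 4 for transgenic against control (Mndal on 2 probe sets, Saa3 and 1 without a symbol), and 9, 115 and 140 genes 2-fold changed in both sexes at 1 week, 8 weeks and 8 against 1 week (15, 189 and 241). Leaving out _x_at, _s_at and _a_at probe sets gave 1462 for sex (2244). With 1 value per gene, 1, 337 (225 higher, 112 lower), 180, 4 and 970 genes passed at 1 week, 8 weeks, 8 against 1 week, transgenic against control and sex; the mean of the Bmpr2 probe sets at 8 weeks was −0.393, and 158 genes were 2-fold changed in both sexes at 8 against 1 week. A 1.5-fold limit gave 134, 770 and 793. With exactly 1 gene symbol 1 probe set passed at 8 weeks (Saa3, adjusted p = 0.0388).

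In the test itself, only the arrays of the groups compared gave 0 at 8 weeks. The trend and robust fit gave 3, 1916 (739 higher, 1177 lower), 752, 96 and 4183 at 1 week, 8 weeks, 8 against 1 week, transgenic against control and sex. Least squares gave 0 at 8 weeks and 0 for sex (4073 and 5626 unadjusted), and 1 for the interaction, Scgb1a1, whose tied values left no variance. Lists passing numbered 17, 15, 14 and 17 at 1 week, 8 weeks, 8 against 1 week and transgenic against control; with an estimated correlation 0, 0, 0 and 0, and with fry 0, 1, 1 and 1, each time neutrophil markers.

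Leaving out 1 array at a time, the 8 week count ranged from 0 to 1071 (without the male 8 week pool), and the sex count from 0 (without either control) to 1279 (without either 8 week pool), 2 probe sets without a symbol passing without either 1 week pool. The interaction could not be fitted without a control. Ranges that crossed 0 were, at 1 week, the brightest Bmpr2 probe set −0.1689 to 0.01222, angiogenesis −0.1291 to 0.005398 and adipose genes −0.02303 to 0.6424; at 8 weeks, the dimmest Bmpr2 probe set −0.2012 to 0.2204, Id3 −0.03491 to 0.0002836 and immediate-early genes −0.6532 to 0.003647; for sex, the third Uty probe set −0.1527 to 0.747; and for transgenic against control, ciliated markers −0.3699 to 0.07067 and cardiac genes −1.105 to 0.001405. The female control, when left out, reversed angiogenesis, immediate-early, ciliated and cardiac genes, and the female 1 week pool reversed adipose genes.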

Other observations

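The tests of explanations in this part were chosen after the results had been seen. Several gene groups tied to pulmonary vascular disease did not pass at 8 weeks. Cytokines and chemokines had a median of 0.302 (adjusted p = 0.062), with the interferon-induced chemokine Cxcl9 at 2.10, Il6 at 1.96 (each at the floor on 1 array), Il18 at 1.72 and the monocyte chemokine Ccl8 at 1.62, and 7 of 23 rose over the list alone. T cell markers stood at 0.374 (adjusted p = 0.207), NK cell markers at 0.241 (0.464), B cell and plasma cell markers at 0.116 (0.991), mast cell markers at 0.54 (0.416) and MHC class II genes at 0.0883 (0.975). Among thymus genes (0.318, 0.189), the gut-homing receptor Ccr9 rose by 1.58 (adjusted p = 0.047). Interferon-stimulated genes did not pass as a group (0.0509, 0.94), although Ifi209 and Mndal rose.

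Lists of vessel tone and remodelling did not pass at 8 weeks either. Vasoactive signalling had a median of −0.00632 (adjusted p = 0.298), with the serotonin transporter Slc6a4 at 1.09 and the prostaglandin synthase Ptgs2 at −0.72. Actin cytoskeleton regulation stood at −0.00967 (0.737), TGF-beta and injury response at 0.06 (0.601), Wnt signalling at 0.0343 (0.991), hypoxia and glycolysis at 0.0516 (0.884), fibroblast and mesenchymal markers at −0.0835 (0.139) and glucocorticoid-responsive genes at −0.112 (0.252). Extracellular matrix genes, higher at 1 week, stood at 0.163 (0.152), with 3 rising over the list alone. Adipose genes (−0.0355, 0.991), skeletal muscle genes (−0.00432, 0.691), heat shock genes (0.112, 0.963) and ribosomal protein genes (0.0431, 0.94) did not pass. Their medians covered members in both directions, such as Ckm (−2.06) and Mybpc2 (1.15) in the skeletal muscle list and Adipoq (−1.2) and Cidec (1.2) in the adipose list, named after their values were seen. With fry and no set direction, 23 lists passed at 8 weeks and 2 at 1 week, Wnt signalling (adjusted p = 0.000629) and smooth muscle contractile genes (0.0128).

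The autosomal probe sets that differed between female and male arrays were weighed against 2 explanations. If transcript amounts differed, other probe sets of the same genes would follow, yet only 54.7% of them differed in the same direction. This spoke against a difference in transcript amount as the source of most of these calls. The called changes had a median of 0.906, and a small difference is harder for another probe set to show. Across all genes with several probe sets, their sex differences correlated at 0.102, against 0.342, 0.397 and 0.334 in the group comparisons, which is consistent with probe sets that responded differently on the female and the male arrays, as they might if the sexes were processed apart. The splits of the 6 arrays into 3 and 3 were too few to test the count: the real 1 gave 2244 and the highest other 0, with 1 of 10 reaching that count. Dates of hybridization for each array would show whether the sexes were processed apart.

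Genes at least 2-fold changed in all 4 transgenic arrays were few: 12 probe sets of 11 genes, with Mndal, Ifi209, Fmo5, Prg4, Saa3, Ube2c, Arsk, Phgdh and Ccr2 higher and Ranbp2 and Yes1 lower. At both durations together, no gene changed 2-fold one way against the female control and the other way against the male control (0). This spoke against chance values in the control arrays. At a single duration, 8 genes went opposite ways at 1 week and 8 at 8 weeks. Among the 11, 2 pairs lay within 20 measured genes of each other, Ifi209 with Mndal and Fmo5 with Phgdh. In a permutation test, 119 of 10000 random draws gave as many (p = 0.012). Those draws treated genes as independent, but related neighbours such as the interferon-inducible Ifi209 and Mndal can change together without any difference of strain. The test therefore cannot decide whether a chromosome segment of another strain was carried with the transgenes, which genotyping these segments would test. The 15 other probe sets, which 7 of the 11 genes had, changed by a median share of 0.0868 of the called one, so some of these 7 may show a change seen by 1 probe set of a gene only, although the other probe set of Arsk moved by 0.819 against 1.71. Mndal was among the 4 genes with no further probe set, and both of its own belonged to the 12.

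The 1 week and 8 week changes shared their controls. Their correlation over genes was 0.307, below the 0.5 that unchanged groups gave in 100 simulations (0.472 to 0.547), while the covariance was 0.0298 against 0.015. Set crosswise between the sexes, where no control was shared, the correlations were 0.0837 (female 1 week with male 8 weeks) and −0.0681 (male 1 week with female 8 weeks). Unchanged groups gave −0.0408 to 0.0463 and −0.0337 to 0.0418, so both lay outside, in opposite directions. The simulated genes varied independently of each other, so none of these simulated ranges allows for genes that vary together. No conclusion was drawn from values outside them. For 3 airway genes, named after their values were seen, the female and the male 8 week pool had log2 intensities of 8.01 and 11.91 (Scgb3a1), 3.95 and 10.67 (Bpifa1), and 3.95 and 8.18 (Reg3g), where 3.95 is the floor. With 1 pool of each sex these differences were not tested. The 8 week medians of the whole list were −0.468 and 0, with the tied Scgb1a1, whose change could not be measured, counted as 0.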
